A study of Mus musculus with 16 samples.

How the data were processed

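RNA was measured in 16 organoid lines from 6 mice with pancreatic ductal adenocarcinoma of the KPC mouse model. Organoids are epithelial cultures grown as small hollow or solid bodies in a gel of basement membrane proteins. Per the labels, 7 lines came from primary tumors and 9 from metastases, and total RNA was depleted of ribosomal RNA before stranded libraries were made.

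The authors deposited a gene table and an isoform table per line. Per the submitters' processing notes, reads were checked with FastQC 0.11.8, aligned with STAR 2.6.0c and quantified with RSEM 1.3.1, and the genome build was GRCm38.p6. Per the file headers, the gene tables hold expected counts, which are estimates and need not be whole, and TPM (transcript abundance scaled by the authors' tool to a fixed total per library). Per the file headers, the isoform tables hold expected counts, TPM and the percent of a gene's transcripts assigned to each isoform. RSEM shares reads among genes and isoforms that resemble each other, so values of near-identical genes are uncertain. Strand settings of the counting step were not given in the sources used here.

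Deposited expected counts were rounded to whole numbers for all count tests. The tables list 55487 genes. Of these, 55394 gene identifiers were matched to GENCODE mouse release M21 for names and positions. The 93 unmatched identifiers held at most 0.0036% of the counts of any library. Total expected counts per library ran from 24624420 to 49965492. Intervals from counts cover counting error only.

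Groups were taken from the stage label, mice from the mouse label and sites from the tissue label. The main test was edgeR 4.0.16's quasi-likelihood test with TMM factors, filterByExpr by stage, a term for each mouse and a term for stage, run in R 4.3.3. Benjamini-Hochberg adjustment covered all 15573 genes tested, with a threshold of 0.05. All adjusted p values for single genes are from edgeR unless another tool is named. Means are CPM on TMM-scaled library sizes with the SD over lines. Lines of 1 mouse are not independent animals, and p values beyond the 6 mice partly measure the spread between lines.

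Gene lists and tests were fixed before the data were examined. Lists with at least 4 members past the filter were tested with camera in limma 3.58.1 on voom values, with the inter-gene correlation preset at 0.01, again with an estimated correlation, and with fry. Of 28 lists, 22 were tested. List scores were the mean log2 CPM of the members with a prior count of 2, compared within each mouse by an exact two-sided sign-flip test over 6 mice, whose smallest possible p is 0.03125. Sites were compared in 1 fit with a term per site, and mice by an F test of the mouse terms. Isoform percentages were compared within mice by the same exact test, for transcripts with a mean of at least 10% and a gene count of at least 20 in every library.

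Genes were named by a rule fixed in advance. It took the 10 largest and 10 lowest log2 fold changes among genes past the threshold that had the same sign in all 6 mice, at least 1 CPM in the higher group and a symbol other than a predicted model. It added 12 genes of the model and of sterol and foregut biology, up to 4 members with the lowest p from each list, the 5 genes with the lowest adjusted p of the site test, and the 5 lowest of the mouse test among genes with at least 10 CPM on average. Some genes named by the rule, and tests that concern only them, are not reported here. Any other gene is said to have been chosen after its values were seen.

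The mouse labels pair the lines by animal. As a check, log2 CPM centred on the stage means was correlated between lines. Lines of 1 mouse had a mean correlation of 0.261 and lines of different mice -0.116, a difference of 0.377 (permutation p = 1e-05, one-sided, the smallest that 100000 resamples can give). Without mouse 6 the difference was 0.209 (permutation p = 0.00249, one-sided). Tumor and metastasis lines of the same mouse correlated between 0.0349 in mouse 3 and 0.252 in mouse 6. With no replicate block, 2219 genes passed the threshold.

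Alternatives covered the mouse term, RLE size factors, 2 other count filters, counts summed per mouse and stage, abundant genes left out, DESeq2 1.42.0, limma with mouse as a random effect, limma on log2(TPM + 1), and each line and mouse left out. For isoforms they were shares from isoform expected counts and a mean of at least 5%. Alternatives added after seeing the data were the 2 libraries with most ribosomal RNA left out, the ribosomal RNA share as a covariate, 3 genes linked to ribosomal RNA left out, and edgeR's robust option. A first look at the data used the robust option. The default was then taken as the main test because the fixed design named no such option, after the robust results had been seen, and both are given.

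Scripts were tested on simulated data with 200 changed genes per comparison. Every simulated gene had the same spread, and genes with few counts were not drawn as changed genes. All lines of a changed group had the same effect, and the test among mice had no other spread between mice. Real genes are less even, so fewer real changes of these sizes may be found. For metastasis against tumor, 58% of genes changed 2-fold and 100% of genes changed 4-fold were recovered among 15465 genes, and 5.39% of calls were false. The test of equal effects over sites recovered 9.5% of 4-fold changes, peritoneum against tumor 75.5% of 4-fold changes, each among 15482 genes, and the test among mice 96.5% of 8-fold changes among 15475 genes.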

Results

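Organoid lines from primary pancreatic tumors and from metastases of the same mice were compared. Mouse 1 gave a liver metastasis line, mice 2, 3 and 4 a peritoneal one each, mouse 5 lines from diaphragm and lung, and mouse 6 lines from liver, diaphragm and ovary. Mouse 6 also gave 2 tumor lines, tumor replicates 6 and 7. Total expected counts averaged 42556859 ± 7744938 (SD, n = 7) in tumor lines and 40015565 ± 6541433 (SD, n = 9) in metastasis lines. Counts of 3 genes that collect ribosomal RNA reads made up 72.7% of metastasis replicate 4 and 29.9% of tumor replicate 2. Their mean share was 15.6% ± 22.6 (SD, n = 9) in metastasis lines and 4.47% ± 11.2 (SD, n = 7) in tumor lines (medians 12.3% and 0.272%). These means leaned on single libraries, as the other 6 tumor lines had at most 0.588%. Mouse 2 went the other way, with 29.9% in its tumor line and 16.6% in metastasis replicate 9. Metastasis replicates 6 and 7 had 0.0185% and 0.0190%, below both tumor lines of mouse 6. No test of this share against stage was run. No line conflicted with its mouse label by Xist and Y-linked genes.

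The comparison of stages asked which genes differ between metastasis and primary tumor lines of the same animals. Non-malignant duct cells in the tumor cultures were not excluded, so any of these differences may reflect cell make-up as well as stage. Eda2r, a p53-induced receptor of the TNF receptor family, averaged 49.9 ± 29.2 CPM (SD, n = 7) in tumor lines and 0.0857 ± 0.0915 CPM (SD, n = 9) in metastasis lines. Ambp, the precursor of alpha-1-microglobulin and bikunin, averaged 112 ± 88.5 CPM (SD, n = 7) and 0.344 ± 0.792 CPM (SD, n = 9). Onecut1, a transcription factor of duct and liver development, averaged 14.4 ± 7.80 CPM (SD, n = 7) and 0.0339 ± 0.0328 CPM (SD, n = 9). Dglucy, a mitochondrial D-glutamate cyclase, fell by 7.58 on the log2 scale (SE 0.69, adjusted p = 0.000151).

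Other genes among the 10 lowest were Ano3, Xlr3a, Dio3os, Grb10, Inhbb and Bex4, each lower in 6 of 6 mice. Dio3os, a noncoding RNA beside the deiodinase gene Dio3, had 445 counts over the tumor lines and 0 in all 9 metastasis lines, at least 163-fold lower against a floor of 3 counts over the group. Dio3os is annotated as starting from a promoter shared in both directions, and its value is uncertain if strand was not used in counting. Ano3, of the anoctamin family, had 3506 counts in tumor lines and 2 in metastasis lines, a ratio of 1924 (95% counting interval 532 to 15893). Grb10, an imprinted adaptor of insulin receptor signalling, had 4446 and 22 counts, and Inhbb, the activin beta B chain, 927 and 4. Xlr3a belongs to a family of near-identical X-linked copies, so its 3412 tumor counts and 5 metastasis counts are uncertain.

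Among genes higher in metastasis lines, Ptpn22, a phosphatase known from lymphocytes, averaged 0.170 ± 0.235 CPM (SD, n = 7) in tumor and 14.4 ± 16.1 CPM (SD, n = 9) in metastasis lines (log2 fold change 5.76, SE 1.17, adjusted p = 0.0095). Isx, an intestinal homeobox factor, and Stra6, a retinol transporter, rose by 5.00 (SE 1.23) and 4.79 (SE 1.26). Ifi211, Cacna2d1, Pmp22, Foxf2 and Lypd8 had log2 fold changes of 5.22, 5.10, 4.71, 4.44 and 4.37 (adjusted p = 0.00870, 0.00970, 0.0227, 0.0417 and 0.0447). Each was higher in 6 of 6 mice, but the sign does not measure the size of the rise. Isx in mouse 4 was at 0.154 CPM in the tumor line and 0.166 CPM in the metastasis line. Cacna2d1 in mouse 6 was at 0.118 and 0.115 CPM in tumor lines and 0.0802 to 0.550 CPM in metastasis lines. Foxf2 and Lypd8 each did not pass in 20 of 35 alternative settings, Stra6 in 16 of 35, Pmp22 in 12 of 34 and Isx in 7 of 35.

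Of 15573 genes tested, 2571 passed the threshold, 1026 higher and 1545 lower in metastasis lines, so 60.1% of calls were lower. Among these, 924 were higher and 1314 lower in all 6 mice, and 1200 changed over 2-fold. The count depended on which lines and mice were used. Mice 1, 2, 3 and 4 each gave a single tumor and a single metastasis line, so leaving out either also removed that mouse's comparison. The same held for tumor replicate 5, the only tumor line of mouse 5. The count was 3910 without tumor replicate 6, and 1521, 1427, 1290 and 1133 without tumor replicates 1, 2, 3 and 5. Without metastasis replicates 1, 2, 3 and 9 it was 1511, 1268, 1669 and 1402. It was 794 without the 2 libraries richest in ribosomal RNA, where 70.0% of calls were lower. That setting also removed the comparison of mouse 2, whose only tumor line is tumor replicate 2. Leaving out mouse 2 alone gave 1394. With all mice kept and the ribosomal RNA share as a covariate, the count was 800. Without mouse 6, 48.6% of calls were lower.

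**Figure D1:**
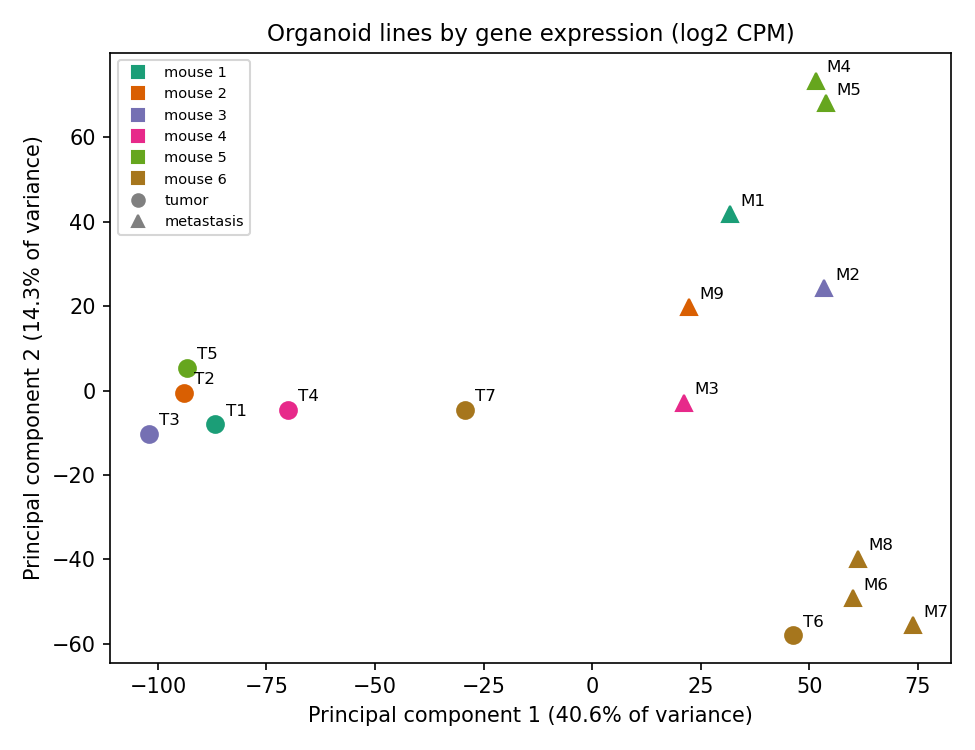
Principal components 1 and 2 of log2 CPM for the 16 lines, in component units, with circles for tumor (T), triangles for metastasis (M), the replicate number beside each and colors for mice. Component 1 holds 40.6% of the variance. Tumor replicate 6 lies at 46.2, within the metastasis lines at 21.2 to 73.9, and tumor replicate 7 at -29.3.

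Targets of p53, the transcription factor mutated in this model, were lower as a group in metastasis lines by camera at its preset correlation (adjusted p = 1.11e-12), but did not pass with an estimated correlation (adjusted p = 0.378). Of 23 measured members, 19 fell, 0 rose and 4 were not called, with a median log2 fold change of -1.35. Ccng1, a cyclin induced by p53, averaged 649 ± 283 CPM (SD, n = 7) in tumor and 96.2 ± 18.5 CPM (SD, n = 9) in metastasis lines. Cdkn1a, which encodes the cell cycle inhibitor p21, fell by 2.24 on the log2 scale (SE 0.34, adjusted p = 0.00313). Mdm2, the ubiquitin ligase that degrades p53, fell by 1.32 (SE 0.21, adjusted p = 0.00385), and Trp53inp1 fell by 3.63 (SE 0.45). Trp53 itself had a log2 fold change of -0.13 (SE 0.14, adjusted p = 0.556).

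Adjusted over the p53 list alone, 19 members were lower. Camera's p values were also small in regroupings of the lines, so the member counts and the direction in each mouse carry more weight. The mean score was lower in 6 of 6 mice, by -1.85 ± 0.51 (SD over 6 mice, exact p = 0.03125, adjusted p = 0.0982). Tumor replicate 6 scored 3.77, while the other tumor lines scored 4.97 to 5.44 and the metastasis lines 2.73 to 3.64.

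**Figure D2:**
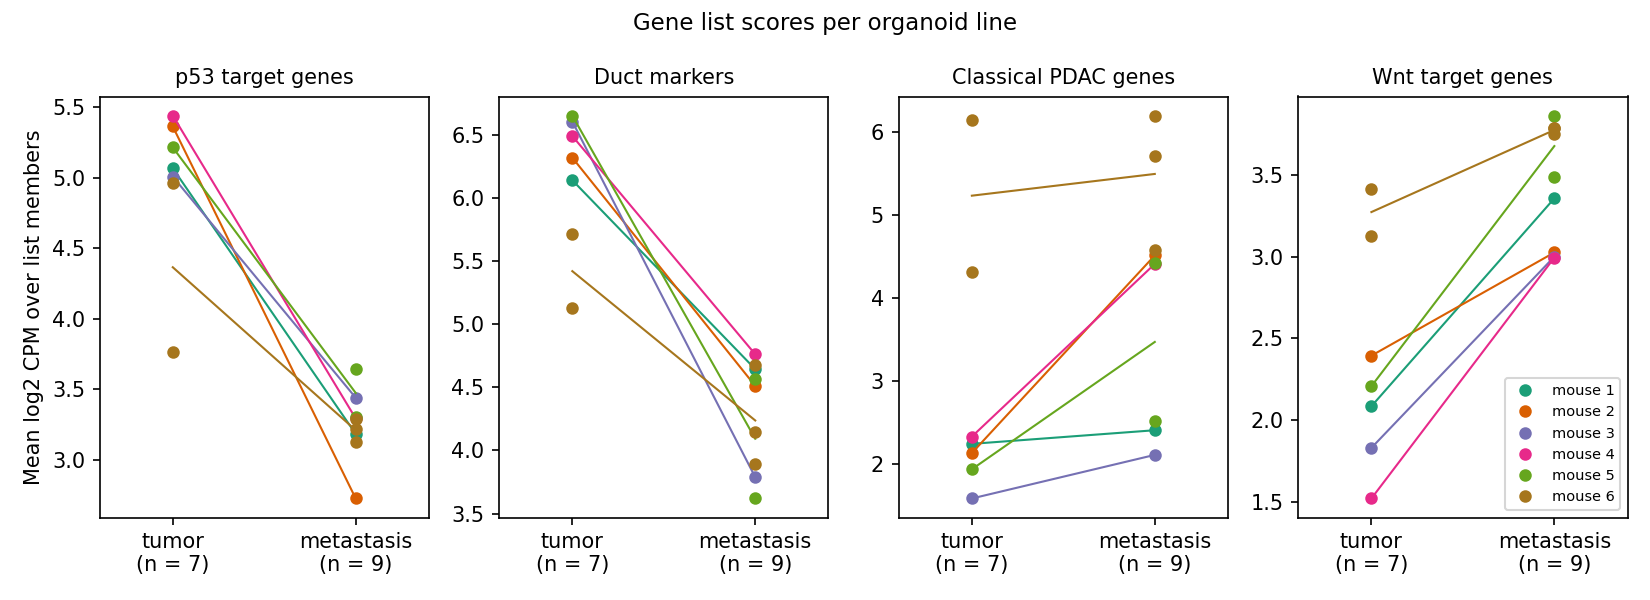
Mean log2 CPM over list members for 4 gene lists, with 1 point per line, colors for the 6 mice and lines joining each mouse's stage means. The p53 and duct scores are lower, and the classical and Wnt scores higher, in metastasis lines of 6 of 6 mice.

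Markers of pancreatic duct cells were lower by camera (adjusted p = 0.00327), but did not pass with an estimated correlation (adjusted p = 0.378). Of 10 members, 6 fell, 1 rose and 3 were not called. Bicc1, an RNA-binding protein of duct epithelium, fell by 2.91 on the log2 scale (SE 0.46), Car2, carbonic anhydrase 2, fell by 1.77 (SE 0.34), and the water channel gene Aqp1 fell by 3.18 (SE 0.68). Cftr, the chloride channel of duct cells, rose, from 14.6 ± 23.8 CPM (SD, n = 7) to 66.8 ± 32.5 CPM (SD, n = 9), and was named after its values were seen. Adjusted over the list alone, 6 were lower and 1 higher.

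Oxidative stress genes driven by Nrf2 were also lower by camera (adjusted p = 0.0119), but did not pass with an estimated correlation (adjusted p = 0.584). Of 15 members, 5 fell and 0 rose. Gsta3, a glutathione transferase, fell by 2.89 on the log2 scale (SE 0.47), Txnrd1, thioredoxin reductase, fell by 0.53 (SE 0.13) and Tkt, transketolase, fell by 0.41 (SE 0.10). Adjusted over the list alone, 9 were lower, and the score was lower in 4 of 6 mice. Tumor replicate 2, with 29.9% of counts linked to ribosomal RNA, had the highest tumor score, 7.15 against 6.43 to 6.72. Without it the list's camera adjusted p was 0.0224. Gclc, which makes glutathione, was at 467 CPM there and had an adjusted p of 0.0329, and did not pass in 21 of 35 alternative settings. Without the 2 libraries richest in ribosomal RNA, Gsta3 passed, and Txnrd1 and Tkt did not.

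Lists higher by camera were the classical subtype, cell cycle and immediate early genes (adjusted p = 0.0409, 0.0125 and 0.0302). With an estimated correlation none of the 3 passed (adjusted p = 0.609, 0.665 and 0.584). At the preset one the classical list passed in 14 of 31 alternative settings. The cell cycle list passed in 28 of 31 (camera adjusted p up to 0.114) and the immediate early list in 24 (up to 0.0974). In the classical subtype of pancreatic cancer, marked by gastrointestinal genes, 3 of 16 members rose, 1 fell and 12 were not called. The iron exporter gene Slc40a1 rose by 1.74 (SE 0.35), the keratin gene Krt20 by 1.78 (SE 0.48) and the lectin gene Lgals4 by 1.84 (SE 0.57), while the trefoil factor gene Tff2 fell by 2.80 (SE 0.86). Lgals4 did not pass in 21 of 35 alternative settings (adjusted p up to 0.203), Tff2 in 20 (up to 0.236) and Krt20 in 14 (up to 0.109). Of 26 cell cycle genes, 2 rose, the transcription factor genes Mybl2 by 0.68 (SE 0.18) and Foxm1 by 0.55 (SE 0.16), with 0 adjusted over the list alone. Foxm1 did not pass in 16 of 35 settings and Mybl2 in 14. Of 11 immediate early genes, which respond within minutes to handling, 3 rose, Nr4a1 by 1.27 (SE 0.29), Fosb by 1.48 (SE 0.41) and Junb by 0.44 (SE 0.14), with 6 higher and 1 lower adjusted over the list alone. Junb did not pass in 23 of 35 settings (adjusted p up to 0.702), Fosb in 15 of 33 and Nr4a1 in 4 of 35.

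Sterol genes were of interest because Soat1 makes cholesterol esters. Soat1 averaged 66.5 ± 54.2 CPM (SD, n = 7) in tumor and 199 ± 43.3 CPM (SD, n = 9) in metastasis lines, a rise of 1.72 on the log2 scale (SE 0.28, adjusted p = 0.00443) seen in 6 of 6 mice. In the mevalonate and cholesterol synthesis list, 3 of 20 members rose, Sqle, squalene epoxidase, by 0.49 (SE 0.12), Mvk, mevalonate kinase, by 0.34 (SE 0.08) and Acat2 by 0.39 (SE 0.11), with 6 higher and 1 lower adjusted over the list alone. Acat2 did not pass in 21 of 35 alternative settings (adjusted p up to 0.780), Sqle in 11 and Mvk in 9. The list's camera adjusted p was 0.0603. In the list of cholesterol uptake, storage and efflux, Soat1 rose and Mylip, a ligase for the LDL receptor, fell by 2.33 (SE 0.48), with a camera adjusted p of 0.0603. Of 12 fatty acid synthesis genes, 0 were called by edgeR (camera adjusted p = 0.971), with a median of -0.02, a mean of 0.01 and camera's direction lower. Fasn, with the second lowest p of them, had a log2 fold change of 0.35 (SE 0.13, adjusted p = 0.0883). Srebf1, Me1 and Fads1 went the other way, with log2 fold changes over the alternative settings of -0.31 to -0.13, -0.55 to -0.32 and -0.57 to -0.29. Of the 12, 5 were positive and 7 negative.

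Cdkn2a, which encodes cell cycle inhibitors, had a log2 fold change of 0.32 (SE 0.16, adjusted p = 0.191). Genes downstream of ERK went both ways, with 4 of 14 rising and 2 falling (camera adjusted p = 0.777). Fosl1, an AP-1 subunit, rose by 1.63 (SE 0.33), while the feedback inhibitor gene Spry2 fell by 0.63 (SE 0.13).

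Transcription factors of the foregut also moved apart, with 5 of 17 falling and 2 rising (camera adjusted p = 0.220). Their mean score was lower in 6 of 6 mice, with a difference of -0.98 ± 0.44 (SD over 6 mice, exact p = 0.03125, adjusted p = 0.0982). Nr5a2 fell by 6.12 (SE 0.83) and Hhex fell by 3.09 (SE 0.52). Gata5 rose by 2.09 (SE 0.41, adjusted p = 0.00803) and Foxa1, which did not pass in 16 of 35 alternative settings, by 3.30 (SE 0.91, adjusted p = 0.0303), and Gata6 had a log2 fold change of -1.68 (SE 0.78, adjusted p = 0.152). Trp63, a squamous factor, was below the count filter. In the basal or squamous list 1 of 9 members, Ly6d, fell, by 3.87 (SE 0.36), with a camera adjusted p of 0.609.

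Wnt targets had 3 of 9 members higher, Axin2 by 1.65 (SE 0.34), Apcdd1 by 2.87 (SE 0.61) and Tcf7 by 1.59 (SE 0.35), with 5 adjusted over the list alone and a camera adjusted p of 0.0630. In epithelial identity 2 of 16 members rose, Ovol2 by 0.77 (SE 0.18) and the keratin gene Krt7 by 0.90 (SE 0.27), with a camera adjusted p of 0.114. Of 5 mesenchymal genes S100a4 and Vim rose, by 2.40 (SE 0.40) and 2.48 (SE 0.68), and the fibronectin gene Fn1 fell, by 2.38 (SE 0.66), with a camera adjusted p of 0.417. The metastasis mean of Vim, 14.2 CPM, was led by metastasis replicate 4, and the other metastasis lines had at most 15.3 CPM. TGF-beta and BMP targets had 3 of 11 lower, among them Id2 with a log2 fold change of -1.21 (SE 0.22), and 2 higher, with a camera adjusted p of 0.690. Hypoxia and glycolysis genes had 2 of 17 lower, Car9 with -3.95 (SE 0.92) and Pfkfb3 with -1.18 (SE 0.26), and a camera adjusted p of 0.114. Unfolded protein and Atf4 genes had 1 of 15 higher, Creld2, and 1 lower, Xbp1, with -1.38 (SE 0.24) and a camera adjusted p of 0.114. Antigen presentation genes had 3 of 13 lower, Tap1 with -2.02 (SE 0.41), B2m with -0.67 (SE 0.15) and H2-Q7, whose reads are shared with its close relatives, and a camera adjusted p of 0.777. Their median was 0.15 and their mean -0.31, with camera's direction lower. Interferon response genes had 2 of 12 lower, Ifit2 and Ifih1, and a camera adjusted p of 0.690. Of the genes in this paragraph, Ifih1 did not pass in 22 of 35 alternative settings, Krt7 in 19 of 35, Fn1 in 17 of 35, H2-Q7 in 17 of 34 and Vim in 16 of 34.

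Over all lists, 6 of 22 passed the threshold by camera, 0 with an estimated correlation and 6 by fry, which were not the same lists. By fry the cell cycle list (adjusted p = 0.203) and the classical list (adjusted p = 0.0982) did not pass, while the Wnt list (adjusted p = 0.00570) and the list of cholesterol uptake, storage and efflux (adjusted p = 0.0426) did. Camera at its preset correlation gave 9 lists with no replicate block. By list scores, 7 of 22 had the same sign in all 6 mice at an exact p of 0.03125, and 0 passed after adjustment. The p53, duct, foregut and hypoxia lists were lower, and the classical, Wnt and epithelial lists higher. Mesothelial markers had 0 of 4 members called by edgeR (camera adjusted p = 0.502) and ovary and oviduct markers 0 of 4 (camera adjusted p = 0.916). Summed levels in tumor and metastasis lines were 1.41 and 1.58 CPM for acinar, 5.67 and 7.03 CPM for fibroblast, 2.48 and 3.31 CPM for immune and 0.350 and 0.655 CPM for endothelial markers. Hepatocyte markers summed to 120 and 132 CPM, mostly Apob, and lung markers to 80.2 ± 72.5 CPM (SD, n = 7) and 3.56 ± 6.85 CPM (SD, n = 9), led by Sftpd.

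Expression also differed by whole chromosomes, which was examined after the values were seen. For pairs of lines from different mice, the SD of the chromosome medians of log2 expression averaged 0.279 in 32 pairs of metastasis lines and 0.0969 in 20 pairs of tumor lines (exact permutation p = 0.00833 over 480 splits within mice, two-sided). Without tumor replicate 6 the tumor pairs averaged 0.0367, and its own 5 pairs with tumor lines of other mice 0.278. After genes were shuffled over chromosomes, the SD averaged 0.0288 for metastasis pairs and 0.0160 for tumor pairs without replicate 6.

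**Figure D3:**
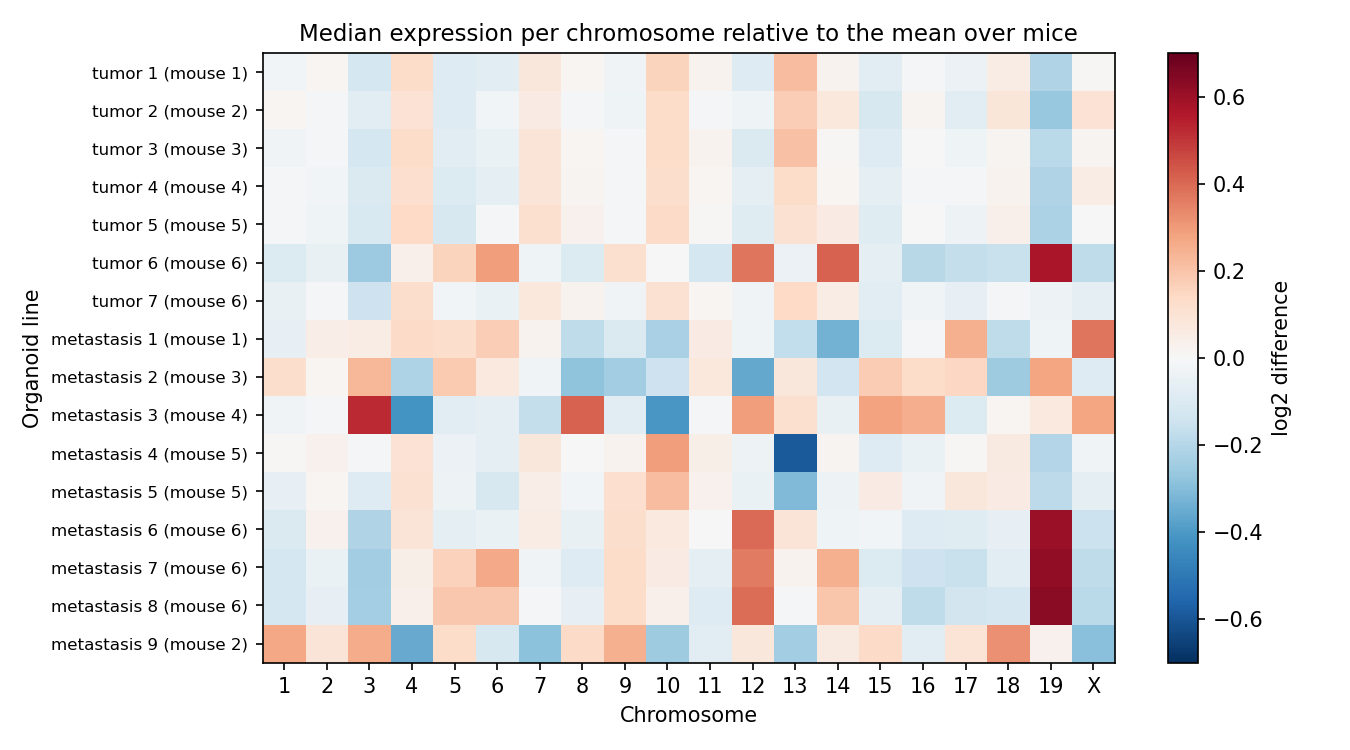
Median log2 difference from the mean over mice for genes of each chromosome across in each line down, on a color scale from blue for lower to red for higher. Tumor lines 1 to 5 share nearly the same profile. Tumor replicate 7 is near them but has -0.03 on chromosome 19, where they have -0.26 to -0.19. Tumor replicate 6 has 0.57 there, as metastasis replicates 6, 7 and 8 have 0.60, 0.62 and 0.63.

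Sites of metastasis were compared to ask whether lines differ by the organ they came from. Car9, a carbonic anhydrase induced by hypoxia, had log2 fold changes against tumor lines of -7.59 (SE 0.61) in peritoneum, -2.99 (SE 0.58) in liver and -1.61 (SE 0.53) in diaphragm, and an adjusted p of 1.00 for equality over sites. Rnu1b1, Rnu1b2, Gm12671 and Gm13040 had the other lowest p values. Rnu1b1 and Rnu1b2 are copies of 1 small nuclear RNA and the others predicted models, so their values are uncertain. In edgeR, 0 genes differed over the 5 sites, with 266 at an unadjusted p under 0.05 and 44 by DESeq2. The 266 are under 1 in 20 of the 15573 genes tested, fewer than chance would give. The test thus ran cautious, and its 0 does not show that sites are alike. Against tumor lines, 171 genes passed in peritoneum, 63 higher and 108 lower. In edgeR, liver gave 0 and diaphragm 0, with 1117 and 1137 at an unadjusted p under 0.05 and 304 and 214 by DESeq2. Liver and diaphragm had 2 lines each, 1 of each from mouse 6, whose tumor lines include tumor replicate 6. Peritoneum had 3, from mice 2, 3 and 4. No setting left tumor replicate 6 out of the site tests, so these counts do not rank the sites. The peritoneal count was 2310 by DESeq2, 18 with the robust option of edgeR and 0 to 174 with single metastasis lines left out. It was 0 without metastasis replicate 9, 1 without replicate 3, 3 without each of replicates 2, 4 and 7, 10 without each of replicates 1 and 6, and 0 without the 2 libraries richest in ribosomal RNA.

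Mouse of origin was compared to see which genes follow the animal. The genes with the lowest p were Xist, which silences an X chromosome in females, and the Y-linked Eif2s3y, Kdm5d, Ddx3y and Uty. Xist averaged 121, 156 and 249 CPM in mice 3, 4 and 6 and at most 0.150 CPM in the others, and Ddx3y 38.4, 48.0 and 43.9 CPM in mice 1, 2 and 5. In all, 24 genes differed, 8 of them on X or Y. The count was 9 with X and Y genes left out, 5 without mouse 6 and 4 without the 2 libraries richest in ribosomal RNA.

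Isoform shares were compared for 14 transcripts of 6 genes. Cdkn2a-202, whose first exon at 89294334 to 89294653 on chromosome 4 begins the p19Arf reading frame, made up 90.3% ± 5.63 (SD, n = 7) of Cdkn2a transcripts in tumor and 98.6% ± 2.03 (SD, n = 9) in metastasis lines. Cdkn2a-202 and Cd44-205 were higher in 6 of 6 mice, each at an exact p of 0.03125 and an adjusted p of 0.109. By the exact test, 0 transcripts passed after adjustment and 4 had a p under 0.05. The tested transcripts of Trp53, Pkm and Ctnnd1 had exact p values from 0.1875 to 0.96875. With shares taken from isoform expected counts, Pkm-201 was lower in 6 of 6 mice (exact p = 0.03125, adjusted p = 0.0813) and Cd44-205 was not tested. With a mean of at least 5%, Pkm-202 was higher in 6 of 6 mice (exact p = 0.03125, adjusted p = 0.0938). Trp63 and Fgfr2 had too few counts.

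In GRCm38, Trp53 lies on chromosome 11 at 69580359 to 69591873, Cdkn2a on chromosome 4 at 89274471 to 89294653, Soat1 on chromosome 1 at 156424525 to 156474331 and Eda2r on chromosome X at 97333840 to 97377216. All are annotated as protein coding.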

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

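Tests of the duct-cell explanation, of tumor replicate 6 and of whole chromosomes were chosen only after the result was seen. Predictions for the other tests were written before those tests were run but after the main results were known. After a first output, the limits for leaving an explanation open were tightened to use the spread of each value, which left the cilia genes and the imprinted genes open, and the test of a metastasis line under a tumor label was allowed to fit.

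Of 298 groups of values examined, 42 (14.1%) had 1 line far from the others, judged by its gap to the nearest line as a share of the group's range. Chance flags about 1 in 20 groups, and the genes are not independent. Tumor replicate 6 accounted for 19, metastasis replicate 4 for 8, tumor replicates 2 and 5 for 5 each, metastasis replicate 5 for 2, and tumor replicate 7 and metastasis replicates 2 and 9 for 1 each. Among named genes, 0 differed over sites in edgeR, where 266 of all genes, fewer than 1 in 20, had an unadjusted p under 0.05 and DESeq2 gave 44.

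Tumor replicate 6 was lowest among tumor lines for Eda2r (gap share 0.766), Ccng1 (0.721), Mdm2 (0.704), the p53 score (0.717), Bicc1 (0.657), Ccn1 (0.588), Dglucy (0.851), Hhex (0.784), Ifit2 (0.654), Mylip (0.619), Nr5a2 (0.594), Onecut1 (0.636) and Tap1 (0.751). It was highest for Dsg3 (0.801), Foxf2 (0.664), Lypd8 (0.589), Ovol1 (0.684), Stra6 (0.743) and Upk1b (0.653). A swap that put a line like the other tumor lines under a metastasis label of mouse 6 was excluded. The lowest of those metastasis lines lay at 60.1 on component 1 and the highest other tumor line at -29.3. A swap with a primary line that resembles the metastases could not be seen this way. A line of another mouse was excluded. The mean correlation of tumor replicate 6 with the metastasis lines of mouse 6 was 0.634 and that with other mice at most -0.0579. A metastasis line under a tumor label would fit. The smallest chi-square per gene of tumor replicate 6 against a metastasis line of mouse 6 was 56.2, below the smallest of 72.3 among those lines. That value cannot tell the stages apart by itself, as it also reflects ribosomal RNA counts. Tumor replicates 1 and 3, of different mice, gave 41.3. Genes with a tumor mean of at least 5 CPM that were lower in metastasis lines without tumor replicate 6 numbered 1515. Tumor replicate 6 lay above every metastasis line for 13.7% of them. Each metastasis line left out in turn lay above all the others for 6.39% to 30.5% of its own genes. Those sets held 585 to 1037 genes, were called with tumor replicate 6 kept as a tumor line, and had 1 fewer line to exceed. The shares are therefore not like for like. Values going the other way were Ambp at 8.55 CPM (metastasis lines at most 2.45), Inhbb at 2.35 (at most 0.0655), Onecut1 at 0.980 (at most 0.0782) and the p53 score (at most 3.64, against 3.77). So were Grb10 at 1.51 CPM (at most 0.184), Dglucy at 1.20 (at most 0.646), Eda2r at 0.667 (at most 0.258) and Nr5a2 at 1.96 (at most 1.39). Dio3os at 0.294 (0 in metastasis lines) and Ano3 at 0.275 (at most 0.258) were above too, but Bex4 at 0.0980 was not (up to 0.218). These genes were picked with tumor replicate 6 counted as a tumor line. A primary region that seeded the metastases could look similar, and no test here separates it from a wrong label.

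Metastasis replicate 4 was lowest in total counts (0.564), protein-coding share (0.728) and genes with 10 counts (0.801), and highest in ribosomal RNA share (0.745) and for Ambp (0.911), Ano3 (1.00), Irf7 (0.501) and Pfkfb3 (0.509). Tumor replicate 2 was lowest in total counts (0.729), protein-coding share (0.753) and genes with 10 counts (0.857), and highest in ribosomal RNA share (0.982) and the Nrf2 score (0.601). Tumor replicate 5 was highest for Cacna2d1 (0.748), Dusp1 (0.590), Inhbb (0.619), Vim (0.790) and the mesenchymal score (0.644). Pmp22 was highest in tumor replicate 7 (0.702), Bex4 (1.00) and Inhbb (0.595) in metastasis replicate 5, Xlr3a in metastasis replicate 2 (0.800) and Tff2 in metastasis replicate 9 (0.523).

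For the lower p53 targets, ribosomal RNA carry-over was excluded, as their median log2 fold change was -1.49 with the ribosomal RNA share as a covariate. Fewer copies of the whole segment within 10 Mb of Trp53, shared over the mice, were excluded. Its 303 tested genes had a median of 0.0464 relative to all genes. By mouse the median was -0.121 in mouse 2 and 0.0291 to 0.132 in the other 5. Such a median cannot show a loss limited to Trp53 and a few neighbours, or loss of an allele with copy number unchanged. Neither of these was tested. Fewer non-malignant duct cells in metastasis cultures stayed open. The written prediction against it was met, because 1 duct marker, Cftr, was called higher, but it was not applied: malignant cells of duct lineage may express Cftr too, and the likeness of chromosome profiles between tumor lines of different mice (mean SD 0.0367 without replicate 6) could also come from non-malignant cells. For the list's p value, 2 of 100 regroupings of lines within mice, the real one included, gave a p as small, and the smallest other p of 2.04e-14 lay below the real 5.05e-14, although the share met the limit set for excluding chance.

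For the other counts, regroupings of the lines within mice gave 1 of 100 with as many genes as the real 2571, the highest other being 0, so chance was excluded. For gene lists, 19 of 100 gave as many as the real 6, the highest other being 11, so chance was not excluded. For peritoneum, 1 of 4 gave as many as the real 171, the highest other being 0, too few to exclude chance.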

How the results depend on the processing

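No called list or named gene turned its direction in a setting, and 0 genes called in common had opposite signs. Some results not called did turn, among them fatty acid synthesis in 17 of 31 settings, Xist in 15 of 34, the basal and ERK lists in 3 each and Cdh2 in 1. The lower share of calls, 60.1%, was 48.6% without mouse 6 (1515 higher, 1435 lower). Cdkn1a, Mdm2 and Soat1 passed in 35 of 35 settings, Sqle in 24, Foxa1 in 19 and Trp53 in 0. With camera's preset correlation the p53 and duct lists passed in 31 of 31, the Nrf2 list in 30, the cell cycle list in 28, the immediate early list in 24 and the classical list in 14. With an estimated correlation, 0 lists passed, and the p53 and duct lists each had an adjusted p = 0.378. For metastasis against tumor, the 2571 genes became 3968 by DESeq2, 893 by limma on log2(TPM + 1), where the median of all genes was -0.14, and 2219 with no replicate block. They ran from 1133 to 3910 with single lines left out, and were 1500, 1394, 1272, 1677 and 766 without mice 1, 2, 3, 4 and 5. In alternatives chosen after seeing the data, they were 794 without the 2 libraries richest in ribosomal RNA, 800 with that share as a covariate and 2549 with the robust option, which was seen first. Lists past the threshold, 6 at first, were 9 with no replicate block, 10 with no count filter, 3 without mouse 5 and 4 to 8 with single lines left out. Of 77 named genes called, 48 passed by limma on log2(TPM + 1), 39 without mouse 5, 40 without the 2 libraries, 41 with the covariate and 49 to 77 with single lines left out. By DESeq2 the site test gave 44 genes, liver 304, peritoneum 2310 and diaphragm 214. Liver gave 0 to 1 with single lines left out, the 1 without metastasis replicate 4, and peritoneum 0 to 174, 18 with the robust option and 0 without the 2 libraries. Mouse of origin gave 9 genes with X and Y genes left out, 5 without mouse 6, 4 without the 2 libraries and 16 with the robust option. Fewer lines or genes were tested where some were left out, and the cause of the other shifts was not tested. At this depth, genes under about 10 counts were not tested.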

Other observations

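Tests of whole chromosomes were chosen only after the result was seen, and the cilia and imprinted gene lists were written before their tests but after some of their genes had been seen to fall. Several imprinted genes, expressed from 1 parental copy, were lower in metastasis lines. Peg3, a zinc finger gene, fell by 5.44 on the log2 scale (SE 0.86, adjusted p = 0.00373), Meg3 had a log2 fold change of -6.05 (SE 1.34, adjusted p = 0.0134) and Rian -6.82 (SE 1.67, adjusted p = 0.0197), the last 2 being noncoding RNAs of the Dlk1 and Dio3 region. Usp29 and Snrpn had -4.60 and -4.79, while Mest rose by 1.16 (SE 0.32). Foxj1, the regulator of motile cilia, fell by 7.48 (SE 0.58, adjusted p = 5.93e-05), and the ciliary kinesin genes Kif27 and Kif6 had -5.48 (SE 0.50) and -3.93 (SE 0.68).

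Lower expression of imprinted genes as a class, suggested by Grb10 and Dio3os, stayed open. The other 21 imprinted genes had a median of -0.21 (95% interval -1.05 to -0.04), with 7 lower and 3 higher, a camera p of 0.0226 and 0.0931 with an estimated correlation. For Foxj1 and Kif27, a loss of the motile cilia program could not be settled. The other 11 cilia genes had a median of -0.0279 (95% interval -1.16 to 0.24), with 2 lower and 0 higher. Only these 11 of 33 listed genes passed the count filter. Their tumor means ran from 0.236 CPM for Ccdc78 to 7.91 CPM for Rfx3, and a fall is hard to see near the low end. For both lists the median met the condition first written against the explanation, but its interval did not clear that limit.

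Whole-chromosome copy number changes would fit the chromosome-wide differences between metastasis lines, whose pairs differed 9.77 times as much as after genes were shuffled. More such changes in metastasis than in tumor lines would also fit (exact p = 0.00833). Tumor lines other than replicate 6 were alike between mice (mean SD 0.0367), which shows likeness and not the number of changes, since values are relative to other lines. Malignant cells with similar profiles and non-malignant duct cells in the cultures could both give this, so these cannot be told apart without DNA. That limit holds for every gene that differed between the stages, not only for the p53 list.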
